A study of Mus musculus with 26 samples.

How the data were processed

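Messenger RNA was sequenced from T cells that had been sorted by flow cytometry from mouse Peyer's patches, the lymphoid follicles in the wall of the small intestine. There were 26 libraries in 4 groups, named by the labels of each sample. CD4+ T cells came from C57Bl/6 mice on a conventional diet (n = 6) or an elemental diet (n = 6). CD44+ T cells (n = 7) and CD44- T cells (n = 7) came from mice on the conventional diet. Per the labels' protocols, the sorted cells went straight into a lysis buffer with beta-mercaptoethanol. Libraries of the CD4+ cells were made from 22 ng of total RNA with poly(A) selection and a standard kit. Those of the CD44+ and CD44- cells were made from 1 ng with a low-input kit. Cell population and kit cannot be told apart between these 2 pairs of groups, so CD4+ libraries were not compared with CD44+ or CD44- libraries. By the reads of Y-linked genes, sex differs between these pairs as well. The labels do not say whether the CD44 sorts were gated on CD4, or whether replicates were separate animals. The p-values therefore measure the spread between these samples, part of which may be technical.

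For each library the authors deposited a table of 25814 genes with the number of reads per gene as whole counts, split into exon reads, intron reads and total gene reads, with and without reads that matched several places. Per the file headers, the same tables hold TPM and RPKM values, which were not tested here. The RPKM values served only to recover each library's mapped read total. The mouse genome build was GRCm38, per the submitters' processing notes, and gene coordinates are those given in the tables. The aligner and the counting program are not given in the sources used here. Total exon reads were the main measure. In 3759 genes the deposited exon length was 0 and no exon read was counted. Among them were 12 immunoglobulin constant genes and 7 T cell receptor constant genes, whose reads appear only in the total gene counts. These genes were left out of the main tests.

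Exon reads per library ran from 16401589 to 25415205 in the CD4+ groups and from 7180390 to 13378353 in the CD44 groups. Introns took 3.24% to 4.42% of mapped reads in the CD4+ libraries and 8.90% to 25.5% in the CD44 libraries. No pair of libraries of a group held the same counts. The lowest chi-square per degree of freedom between libraries of a group was 11.9, over genes with at least 20 reads in the pair, so no library was counted as a duplicate.

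Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each comparison was fitted on its own 2 groups. Genes were filtered with edgeR's filterByExpr by group and scaled by TMM factors. They were tested two-sided with edgeR's quasi-likelihood test, using robust estimation of the gene-wise spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A positive log2 fold change means higher on the elemental diet or higher in CD44+ cells. Its standard error was the size of the log2 fold change divided by the square root of the F statistic. Expression levels are read counts relative to the TMM-scaled library size (CPM), as mean ± SD over libraries. Log2 CPM values used a prior count of 2.

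Before the data were examined, 35 gene lists were fixed. Of these, 34 described T cell states and metabolic programs, RNA quality and handling, or markers of cell types that a sort could carry, and 1 held sex-linked genes as a check. The state and program lists covered naive and recirculating, effector and memory, T cell receptor signal, co-inhibitory and anergy, follicular helper, regulatory, Th17, Th1 and cytotoxic, and Th2 genes. They also covered pro-apoptotic, survival, p53 target, cell cycle, interferon-stimulated, mucosal homing, aryl hydrocarbon and retinoic acid response, glycolysis, cholesterol synthesis, amino acid response, glucocorticoid response and circadian clock genes. The quality lists were handling stress, ribosomal protein and mitochondrially encoded genes. The marker lists were alpha-beta T cell core genes, CD8 T cells, gamma-delta T, NK and innate lymphoid cells, B cells, germinal centre B cells, plasma cells, myeloid and dendritic cells, epithelial cells, stromal and endothelial cells, and erythroid cells. Lists with at least 3 tested members, 33 in each comparison, were tested with limma's camera on voom values at a preset correlation of 0.01, and the p-values were adjusted over the lists. The CD8 list had 2 members and was not tested as a list. Every list was tested again with an estimated correlation and with fry, limma's directional test. Member counts are given over all genes tested and adjusted over the list alone.

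The genes named in the text followed a rule fixed at the same time. It took the 6 largest increases and 6 largest decreases among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, leaving out unnamed genes, pseudogenes and receptor segments. It added 16 fixed genes and up to 3 members with the smallest p of each described list. Some genes that the rule took are not reported here. A CD44 score was set for each CD4+ library as the mean log2 CPM of up to 200 genes higher in CD44+ cells minus that of up to 200 genes lower in them. The genes had to be called in the CD44 comparison and tested in both comparisons. Their diet means were compared by an exact two-sided permutation test.

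Counting steps were tested on simulated counts drawn from the real means and library sizes. For the diet comparison, run on 11779 genes, edgeR found 76 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 3.83% of its calls were unchanged genes. For the CD44 comparison, run on 8195 genes, it found 0 of 100 genes changed 2-fold and 9 of 100 changed 4-fold, with 1 unchanged gene among 10 calls. In the same CD44 simulation DESeq2 made 34 calls, of which 14 were unchanged genes. In list simulations on 11751 genes for the diet and 8187 for CD44, camera recovered the changed list in both and called 0 others. In the same simulations fry recovered the changed list and called 1 unchanged list for the diet. It missed the changed list for CD44 (adjusted p = 0.0506) with 0 others called. Each gene was drawn independently in these simulations. They therefore cannot show how often camera at the preset correlation calls unchanged lists whose members are correlated. In the diet libraries the estimated correlation was 0.879 for ribosomal protein genes and 0.311 for follicular helper genes.

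Alternatives covered other scaling factors, no filter or a stricter filter on low counts, and DESeq2 or limma-voom with quality weights. They also covered a minimum fold of 1.5 (glmTreat), 1 fit over all 4 groups, unique reads only, receptor segments left out, the replicate number as a block, and leaving out each library in turn. Total gene reads, the joint omission of 2 libraries in each comparison and a score on the 100 genes each way with the smallest p were added after seeing the data.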

Results

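Gene expression was measured by RNA sequencing in T cells sorted from the Peyer's patches of C57Bl/6 mice. The series asks how antigen from food affects these cells, and compares CD4+ T cells of mice on a conventional diet (n = 6) with those of mice on an elemental diet (n = 6), a diet in which free amino acids replace protein. CD44+ (n = 7) and CD44- (n = 7) T cells from mice on the conventional diet form a further pair. CD44 is an adhesion receptor that is high on T cells that have met antigen. Total exon reads averaged 20820951 ± 3129833 (SD) in the conventional group and 19381832 ± 1789002 in the elemental group. They averaged 8308088 ± 882705 in CD44+ libraries and 9848213 ± 1899440 in CD44- libraries. Levels below are mean CPM ± SD over the libraries of a group, and log2 fold changes are given ± SE.

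On the elemental diet, CD4+ T cell libraries had lower expression of follicular helper, cell cycle and germinal centre genes, and higher expression of epithelial and myeloid genes. These 5 lists were called with a preset correlation and lost their calls with adjusted p = 0.127, 0.127, 0.244, 0.477 and 0.212 with an estimated correlation, in the order given. Il21, the cytokine through which follicular helper cells act on B cells, fell from 44.9 ± 10.2 to 16.9 ± 4.23 CPM. Top2a, a topoisomerase of dividing cells, fell from 8.99 ± 3.91 to 1.16 ± 0.503 CPM. Fbp1, a gluconeogenic enzyme, rose from 1.44 ± 1.44 to 39.5 ± 8.47 CPM (each n = 6). Of 11938 genes tested, 2081 were called, 1156 higher and 925 lower on the elemental diet. The first principal component of the 500 most variable genes separated the diets with 60.1% of the variance. Within the conventional group, libraries stood in the same order on this component and in mean log2 CPM of abundant enterocyte transcripts. They ran from replicate 1 (-62.9 and 1.34) to replicate 6 (-1.28 and 4.76), and elemental replicate 3 was at 11.2 and 5.22. The enterocyte list was written after the data were seen, and diet and enterocyte RNA cannot be told apart on this component. The count of called genes was 1299 without conventional replicate 4, 1316 without elemental replicate 4, 3865 without conventional replicate 6, and 3379 without conventional replicate 6 and elemental replicate 1 together. It was 347 against a minimum fold of 1.5, with 77.2% of those calls higher against 55.6% in the main test, 4070 with limma-voom and quality weights, and 2 when all 4 groups shared an estimate of the spread.

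Follicular helper genes were lower on the elemental diet. Of 19 tested members, 15 fell and 0 rose, and 17 fell when p was adjusted over the list alone. The median log2 fold change was -0.83 (camera adjusted p = 6.86e-14), with adjusted p = 0.127 with an estimated correlation. Sostdc1 fell from 64.3 ± 16.6 to 19.02 ± 5.73 CPM (log2 fold change -1.76 ± 0.19, adjusted p = 8.77e-05). Pou2af1, a transcriptional coactivator that B cells also express, fell from 116 ± 18.4 to 44.7 ± 9.97 CPM (-1.37 ± 0.15), and Il21 changed by -1.41 ± 0.18. Bcl6, the lineage-defining repressor of follicular helper cells, fell from 30.9 ± 10.9 to 14.1 ± 2.70 CPM (-1.14 ± 0.22, adjusted p = 0.00383). Cxcr5, the chemokine receptor that brings these cells into follicles, fell from 185 ± 26.7 to 89.5 ± 27.3 CPM (-1.05 ± 0.17, adjusted p = 0.00139). Each of these genes lay below the conventional mean in 6 of 6 elemental libraries. Alpha-beta T cell core genes had a median of -0.14 in the same libraries, and 4 of 13 members fell (1 higher and 5 lower adjusted over the list alone), among them Cd28 (-0.47 ± 0.09), Cd6 (-0.52 ± 0.12) and Zap70 (-0.25 ± 0.06). That list was not called by camera (adjusted p = 0.186), but fry called it downward (adjusted p = 0.034). Its mean log2 CPM changed by -0.14 (exact permutation p = 0.00649).

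Cell cycle genes fell in 29 of 31 tested members (30 adjusted over the list alone), and 0 rose. Their median log2 fold change was -1.10 (camera adjusted p = 7.66e-20), with adjusted p = 0.127 with an estimated correlation. Top2a changed by -2.96 ± 0.37 (adjusted p = 1.60e-04) and the checkpoint kinase Bub1b by -1.99 ± 0.26. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, fell from 33.9 ± 6.30 to 12.5 ± 3.34 CPM. Mcm6, a part of the replicative helicase, fell from 117 ± 11.2 to 62.8 ± 8.67 CPM (-0.90 ± 0.10, adjusted p = 8.22e-05). Mki67 was too low to be tested, with 9 to 17 reads per conventional library and 0 to 8 reads per elemental library. Cholesterol synthesis genes fell in 9 of 20 members, with the same count adjusted over the list alone, and 0 rose. The median was -0.33 (camera adjusted p = 1.55e-05), and adjusted p = 0.244 with an estimated correlation. Cyp51 changed by -0.63 ± 0.09, Idi1 by -0.45 ± 0.09 and Fdft1 by -0.38 ± 0.08, all enzymes of the sterol pathway.

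Markers of B lineage cells fell in the same libraries. Mean log2 CPM changed by -2.99 for germinal centre B cell markers and by -1.27 for cell cycle genes. Which cells held the RNA of the cell cycle genes that fell was not tested, so their fall is not assigned to T cells. All 6 tested germinal centre B cell markers fell, also adjusted over the list alone, with a median log2 fold change of -3.24 (camera adjusted p = 1.49e-05), and adjusted p = 0.244 with an estimated correlation. Gcsam, on chromosome 16 from 45610380 to 45622867 (ENSMUSG00000022659), changed by -3.65 ± 0.53 (adjusted p = 6.48e-04). Mef2b changed by -3.05 ± 0.38 and Rgs13, a regulator of chemokine signalling, by -2.89 ± 0.40. Plasma cell markers fell in 4 of 6 members, with the same count adjusted over the list alone, and had a median of -1.43 (camera adjusted p = 0.00568), with adjusted p = 0.477 with an estimated correlation. Mzb1, a chaperone of antibody assembly, fell from 82.8 ± 28.5 to 30.2 ± 7.52 CPM, and Derl3 and Eaf2 changed by -1.86 ± 0.36 and -1.91 ± 0.47. B cell markers fell in 4 of 14 members and in 8 of 14 adjusted over the list alone, with a median of -0.64 (camera adjusted p = 2.12e-04) and adjusted p = 0.477 with an estimated correlation. Ms4a1, which encodes CD20, fell from 116 ± 37.4 to 58.1 ± 21.9 CPM (adjusted p = 0.0258), a call lost without conventional replicate 4 (0.0579) or 5 (0.0567). Cd22 changed by -0.90 ± 0.24 (adjusted p = 0.0179), a call lost without conventional replicate 4 (0.0502).

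**Figure D1:**
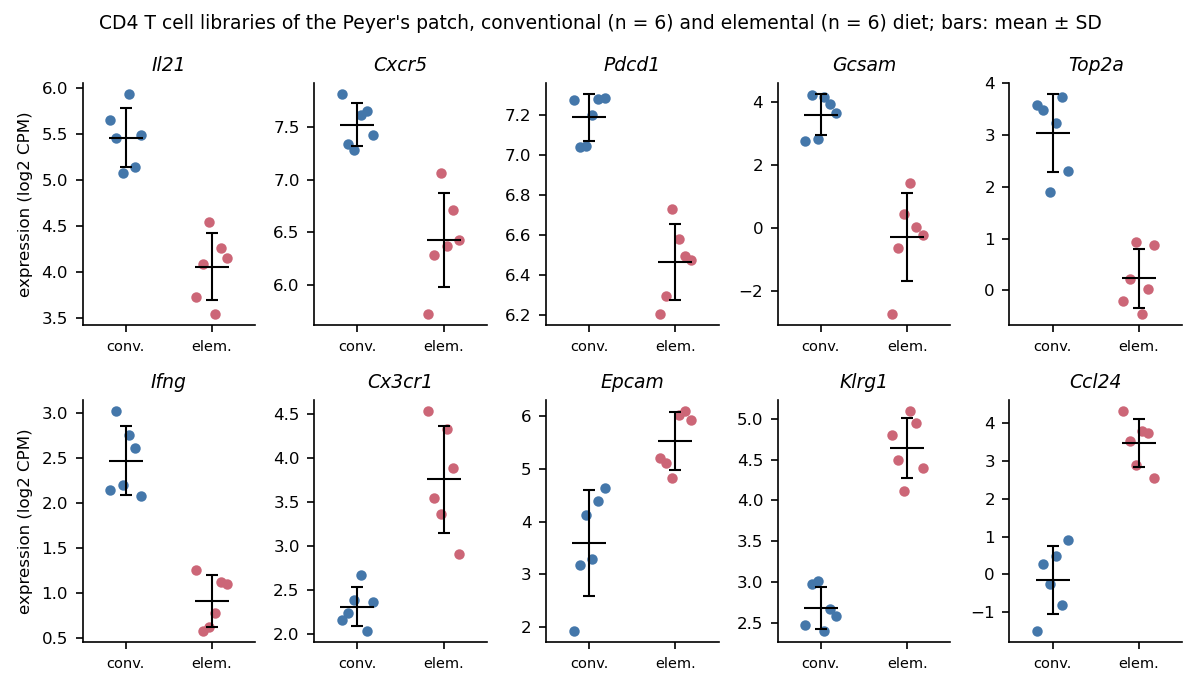
Expression (log2 CPM) of 10 genes in the CD4+ T cell libraries of the conventional and elemental diet groups, with 1 point per library and the mean ± SD as bars (n = 6 per diet). Il21, Cxcr5, Pdcd1, Gcsam, Top2a and Ifng lay lower, and Cx3cr1, Epcam, Klrg1 and Ccl24 higher, in every elemental library than in any conventional library.

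Co-inhibitory and anergy genes fell in 8 of 16 members and rose in 1 (10 lower and 2 higher adjusted over the list alone). The median was -0.50 (camera adjusted p = 4.64e-04), with adjusted p = 0.244 with an estimated correlation. Tigit fell from 84.5 ± 10.04 to 45.8 ± 4.95 CPM (-0.88 ± 0.10, adjusted p = 7.83e-05). Pdcd1, which encodes the inhibitory receptor PD-1 and also stands among the follicular helper genes, fell from 146 ± 11.7 to 88.7 ± 11.7 CPM (-0.72 ± 0.09). Rnf128, a ubiquitin ligase linked to T cell anergy, moved the other way, from 12.9 ± 4.01 to 39.95 ± 7.85 CPM (1.63 ± 0.19, adjusted p = 1.01e-04). T cell receptor signal genes fell in 6 of 17 members (7 lower and 1 higher adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0411), and adjusted p = 0.685 with an estimated correlation. Egr2 changed by -0.92 ± 0.13, Irf4 by -0.69 ± 0.12 and Egr1 by -0.64 ± 0.16. Nr4a1, an early gene of receptor signalling, had a log2 fold change of 0.38 ± 0.32 and was not called (adjusted p = 0.425). The call of this list was lost without conventional replicate 2 (adjusted p = 0.130), elemental replicate 3 (0.0567) or elemental replicate 4 (0.257), and with total gene reads (0.115).

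Among the effector lineages, Th1 and cytotoxic genes fell in 7 of 18 members and rose in 1 (7 lower and 2 higher adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.0438), with adjusted p = 0.477 with an estimated correlation. Ifng, the defining cytokine of Th1 cells, fell from 5.61 ± 1.56 to 1.82 ± 0.378 CPM (-1.63 ± 0.25, adjusted p = 6.35e-04). Ccl5 fell from 140 ± 57.4 to 50.1 ± 15.1 CPM and Gzmk, a granzyme, from 22.0 ± 4.97 to 9.92 ± 4.91 CPM. Tbx21, the Th1 transcription factor, was not called (-0.38 ± 0.19, adjusted p = 0.161). The list's call was lost without any 1 of conventional replicates 2, 3, 5 and 6 or elemental replicates 2, 5 and 6, with adjusted p between 0.0517 and 0.0868, and without conventional replicate 6 and elemental replicate 1 together (0.0663). Th17 genes went both ways, 3 higher and 1 lower of 12, with the same counts adjusted over the list alone. This list was not called (camera adjusted p = 0.706), and its median of -0.15 and mean of -0.32 lie against camera's upward direction. The neighbouring and overlapping genes Tmem176b (0.98 ± 0.13) and Tmem176a (0.88 ± 0.13) rose, and reads from their overlap could be assigned to either. The 1 member that fell was the cytokine gene Il17a, named after its value was seen.

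Regulatory T cell genes rose in 4 of 16 members, and 8 were higher and 1 lower adjusted over the list alone. The median was 0.37 (camera adjusted p = 0.00529), with adjusted p = 0.244 with an estimated correlation. Klrg1, a receptor of terminally differentiated regulatory and effector cells, rose from 6.44 ± 1.18 to 25.5 ± 6.31 CPM (1.99 ± 0.18, adjusted p = 2.26e-05). Ebi3, a subunit of interleukin-27 and interleukin-35, rose from 5.78 ± 1.79 to 12.7 ± 1.31 CPM, and Tnfrsf18, which encodes GITR, changed by 0.48 ± 0.11. Foxp3, the lineage-defining factor, was at 24.2 ± 5.19 and 33.9 ± 7.47 CPM and was not called (0.48 ± 0.17, adjusted p = 0.0618). Ikzf2, which encodes Helios, was not called either (-0.47 ± 0.16, adjusted p = 0.0529). Interferon-stimulated genes rose in 7 of 24 members (8 higher and 1 lower adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00568), and adjusted p = 0.477 with an estimated correlation. Bst2 rose from 71.0 ± 15.3 to 127 ± 19.4 CPM, Irf7 changed by 0.72 ± 0.10 and Ifi44 by 1.64 ± 0.30.

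Epithelial and myeloid markers rose in the libraries in which follicular helper and cell cycle genes fell. Which cells held the RNA of Rnf128 and of the Th17, regulatory T cell and interferon-stimulated genes that rose was not tested. Their rise is therefore not assigned to T cells. Of 20 epithelial markers 7 rose and 0 fell, and 13 rose adjusted over the list alone. The median was 1.54 (camera adjusted p = 5.57e-09), with adjusted p = 0.477 with an estimated correlation. Epcam rose from 14.2 ± 8.03 to 48.9 ± 17.7 CPM (1.79 ± 0.42, adjusted p = 0.0142), Vil1 changed by 1.51 ± 0.35 and Cdh1 by 1.32 ± 0.30. Of 13 myeloid and dendritic markers 12 rose, also adjusted over the list alone, with a median of 1.23 (camera adjusted p = 3.03e-07), and adjusted p = 0.212 with an estimated correlation. Ctss, a lysosomal protease of antigen presentation, rose from 356 ± 38.1 to 556 ± 69.7 CPM, Cx3cr1, the receptor of gut macrophages, changed by 1.56 ± 0.25, and Siglech, a marker of plasmacytoid dendritic cells, by 1.60 ± 0.29. Among well expressed called genes without overlap between the diets, the largest increases included genes of the intestinal epithelium. Fbp1, on chromosome 13 from 62864753 to 62888282 (ENSMUSG00000069805), changed by 4.86 ± 0.70 (adjusted p = 0.00139). Slc2a5, the fructose transporter GLUT5 on chromosome 4 from 150119283 to 150144169 (ENSMUSG00000028976), changed by 3.94 ± 0.63 (adjusted p = 0.00217). The mucin gene Muc3 changed by 3.33 ± 0.76 and the apolipoprotein gene Apoc3 by 3.32 ± 0.62. Ccl24, a chemokine of macrophages and eosinophils, changed by 3.66 ± 0.41 (adjusted p = 9.64e-05).

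Other fixed genes had differences of less than 2-fold. Cd44 fell from 138 ± 14.7 to 91.2 ± 17.2 CPM (-0.60 ± 0.12, adjusted p = 0.00339). Cd4 was at 353 ± 78.6 and 239 ± 45.9 CPM (-0.56 ± 0.16, adjusted p = 0.0250), a call lost without conventional replicate 1, 4 or 5 or elemental replicate 4 or 6 (adjusted p between 0.0505 and 0.0585). The death receptor gene Fas changed by -0.43 ± 0.12 (adjusted p = 0.0286), lost without conventional replicate 1, 2 or 4 or elemental replicate 1, 4 or 5 (0.0527 to 0.0737). The survival gene Bcl2 changed by 0.40 ± 0.13 (adjusted p = 0.0492), lost without any 1 of conventional replicates 2 to 5 or elemental replicates 1 to 5 (0.0529 to 0.111). Bcl2l11, which encodes the pro-apoptotic protein BIM, and Gata3, the Th2 factor, were not called (-0.09 ± 0.12, adjusted p = 0.626, and 0.05 ± 0.18, adjusted p = 0.868).

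Naive and recirculating genes rose in 4 of 16 members and fell in 1 (6 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.393; its median of -0.02 and camera's upward direction differ in sign). Igfbp4 (0.69 ± 0.13) and Ccr7 (0.53 ± 0.10) rose and Tcf7 fell (-0.63 ± 0.15). Effector and memory genes split 3 higher and 3 lower of 20 (5 and 4 adjusted over the list alone; camera adjusted p = 0.958, downward against a median of 0.04), with S100a11 (-0.78 ± 0.10) and Icos (-0.83 ± 0.12) lower. Gamma-delta T, NK and innate lymphoid markers rose in 3 of 4 members and fell in 1, also adjusted over the list alone, and were not called (camera adjusted p = 0.117). Tyrobp (1.498 ± 0.226) and Fcer1g (1.504 ± 0.221), signalling adaptors that myeloid cells also express, rose, and Klrb1c, which encodes NK1.1, fell (-0.94 ± 0.13). Glucocorticoid response genes were 2 higher and 1 lower of 9 (3 and 1 adjusted over the list alone; camera adjusted p = 0.360), with Sgk1 at 0.72 ± 0.16, Klf9 at 1.01 ± 0.26 and Fkbp5 at -0.57 ± 0.14.

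The remaining lists had few called members, and their genes are named here after their values were seen. Dhrs3 and Cyp26b1, which act on retinoids, rose among 9 aryl hydrocarbon and retinoic acid response genes (2 also adjusted over the list alone; camera adjusted p = 0.305). Dbp and Nr1d1 rose among 13 circadian clock genes (2; 0.360), Ccr8 and Il1rl1 among 5 Th2 genes (2; 0.506) and Bcl2 and Bcl2l1 among 12 survival genes (1; 0.724). Trp53inp1 and Gtse1 fell among 12 p53 target genes (2; 0.629). Tnfrsf1a rose and Fas fell among 22 pro-apoptotic genes (1 and 1; 0.958), and Atf4 rose and Gars fell among 19 amino acid response genes (1 and 0; 0.627). Cxcr6 rose among 10 mucosal homing genes (1 higher and 1 lower adjusted over the list alone; 0.958). Cxcl13 fell among 5 stromal and endothelial markers (1; 0.375), and Cd8b1 rose of the 2 CD8 markers (1 higher and 1 lower adjusted over the list alone). Of 13 glycolysis genes 0 were called by edgeR (3 lower adjusted over the list alone, 1 higher and 3 lower at an unadjusted p under 0.05, 3 lower with DESeq2, and 1 higher and 3 lower with limma-voom; camera adjusted p = 0.316). Of 4 erythroid markers 0 were called (4 higher adjusted over the list alone and at an unadjusted p under 0.05, 0 with DESeq2, 1 with limma-voom; 0.305).

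Of the signs of RNA quality and handling, handling stress genes rose in 5 of 21 members and 6 adjusted over the list alone. The median was 0.37 (camera adjusted p = 0.0209), with adjusted p = 0.594 with an estimated correlation. Nfkbia rose from 243 ± 39.1 to 363 ± 42.9 CPM and Hspa1b, which shares reads with its near-identical copy Hspa1a, from 61.7 ± 27.0 to 196 ± 111 CPM. The call was lost without conventional replicate 6 (0.0630), elemental replicate 1 (0.0679) or elemental replicate 2 (0.0681), and without conventional replicate 6 and elemental replicate 1 together (0.150). Ribosomal protein genes had a median of 0.25 (camera adjusted p = 3.51e-08), with adjusted p = 0.673 with an estimated correlation. Of its 78 members edgeR called 0, also adjusted over the list alone, while 17 were higher at an unadjusted p under 0.05, 0 were called with DESeq2 and 48 with limma-voom. Rps20 had the smallest p (0.35 ± 0.14, adjusted p = 0.0828). Among 13 mitochondrially encoded genes mt-Nd4l fell (0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.314). In all, 15 of 33 lists were called with the preset correlation, 6 up and 9 down. With an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05, and fry called 14. Of the lists called with the preset correlation, fry did not call T cell receptor signal (adjusted p = 0.156), ribosomal protein (0.156), handling stress (0.0922) and B cell marker genes (0.0537). Camera did not call the alpha-beta T cell core genes, which fry called downward (adjusted p = 0.034). Nor did it call the gamma-delta T, NK and innate lymphoid markers (fry 0.0167) and aryl hydrocarbon and retinoic acid response genes (fry 0.0127), both upward.

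**Figure D2:**
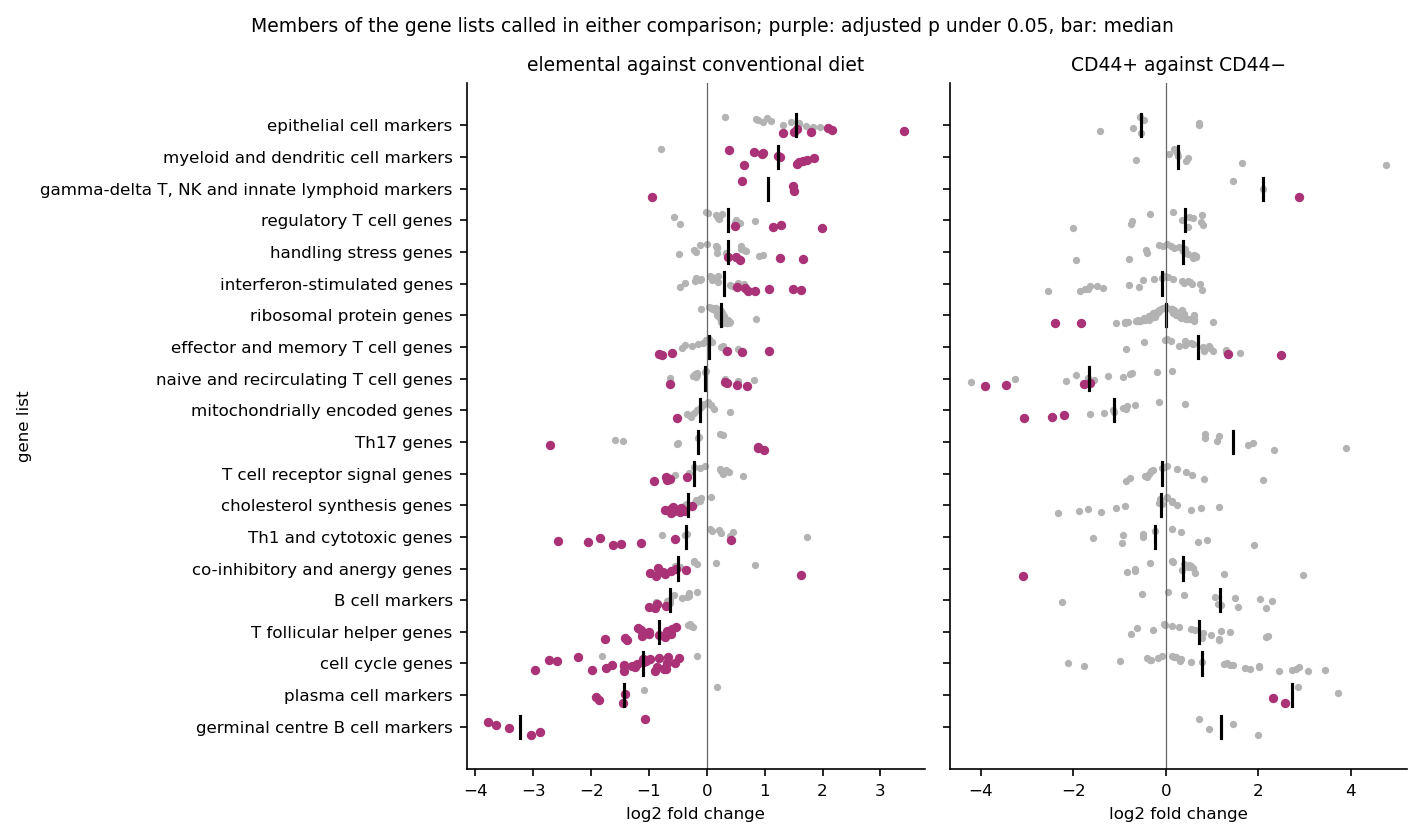
Log2 fold changes of the members of each gene list called in either comparison, for the diet comparison and for CD44+ against CD44- cells, with 1 point per gene, purple where its adjusted p is under 0.05, and the list median as a bar. Cell cycle and follicular helper genes have medians of -1.10 and -0.83 in the diet comparison, and naive and recirculating genes a median of -1.66 in the CD44 comparison.

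The CD44 comparison asks which genes set apart T cells with and without surface CD44 on the conventional diet. CD44+ libraries had lower expression of genes of naive cells and higher expression of plasma cell markers. Which cells held the RNA of cell type markers was not tested, so their rise is not assigned to T cells. The marker lists of B cells, germinal centre B cells, myeloid and dendritic cells, and gamma-delta T, NK and innate lymphoid cells were called upward as well, with 1 called member among them. With an estimated correlation the last of these lists kept its call (adjusted p = 0.0106), and the others lost it, with adjusted p = 0.285, 0.139 and 0.364 with an estimated correlation in the order given. Igfbp4, a gene of naive cells that encodes a binding protein of insulin-like growth factors, fell from 179 ± 50.6 CPM in CD44- cells to 16.3 ± 18.5 CPM in CD44+ cells (each n = 7), and Jchain, the joining chain of secreted antibodies, rose from 1003 ± 937 to 5020 ± 1420 CPM. Of 8343 genes tested, 64 were called, 25 higher and 39 lower in CD44+ cells, and 1114 had an unadjusted p under 0.05. The spread between replicates was wide, with a common biological coefficient of variation of 0.987 against 0.285 in the diet comparison. The count was 36 without CD44+ replicate 5, 37 without CD44+ replicate 6, 36 without CD44+ replicate 7, 41 without CD44- replicate 4, and 41 without CD44- replicate 2 and CD44+ replicate 8 together. It was 30 against a minimum fold of 1.5, with 26.7% of those calls higher against 39.1% in the main test, 101 with total gene reads, 815 with DESeq2, and 1748 when all 4 groups shared an estimate of the spread.

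Naive and recirculating genes fell in 4 of 16 members and 12 adjusted over the list alone, and 0 rose. The median was -1.66 (camera adjusted p = 5.25e-11), and the call held with an estimated correlation (0.0106). Igfbp4 changed by -3.46 ± 0.58 (adjusted p = 0.00644). Lef1, a transcription factor of naive T cells, fell from 554 ± 137 to 162 ± 95.8 CPM (-1.78 ± 0.39, adjusted p = 0.0353), a call kept only without CD44+ replicate 2, 4 or 8 or CD44- replicate 6 or 8 and otherwise lost (0.0507 to 0.0806). Effector and memory genes rose in 2 of 20 members (7 higher and 1 lower adjusted over the list alone), with a median of 0.69 (camera adjusted p = 1.46e-06) and adjusted p = 0.139 with an estimated correlation. S100a6 rose from 20.1 ± 12.6 to 112 ± 54.3 CPM (adjusted p = 0.0321), a call lost without CD44+ replicate 2, 4, 7 or 8 or CD44- replicate 1 or 4 (0.0525 to 0.0839). Id2, a repressor used by effector and innate lymphocytes, rose from 292 ± 136 to 739 ± 189 CPM (adjusted p = 0.0391), a call kept only without CD44+ replicate 2 or CD44- replicate 6, 7 or 8 and otherwise lost (0.0534 to 0.0866). Tnfrsf4 had a log2 fold change of 1.59 ± 0.43 and was not called (adjusted p = 0.0920).

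Cd44 itself was at 81.2 ± 30.2 CPM in CD44- and 157 ± 94.5 CPM in CD44+ libraries and was not called (0.95 ± 0.40, adjusted p = 0.303), though 7 of 7 CD44+ libraries lay above the CD44- mean. Cd4 was at 166 ± 157 and 38.8 ± 22.2 CPM (-2.10 ± 0.57, adjusted p = 0.0950). Foxp3, with 1 to 11 reads per library, and Tbx21, with 0 to 7 reads, were too low to be tested. None of the remaining fixed genes was called. Their log2 fold changes were 1.15 ± 0.35 for Bcl6 (adjusted p = 0.135), 1.27 ± 0.71 for Mki67 (0.471), 0.89 ± 0.95 for Bcl2l11 (0.763), 0.34 ± 0.43 for Ikzf2 (0.802) and 0.14 ± 0.52 for Pdcd1 (0.941). They were -0.05 ± 0.75 for Cxcr5 (0.987), -0.19 ± 0.82 for Gata3 (0.951), -0.40 ± 0.59 for Nr4a1 (0.840), -0.83 ± 0.68 for Fas (0.668) and -1.06 ± 0.45 for Bcl2 (0.315).

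**Figure D3:**
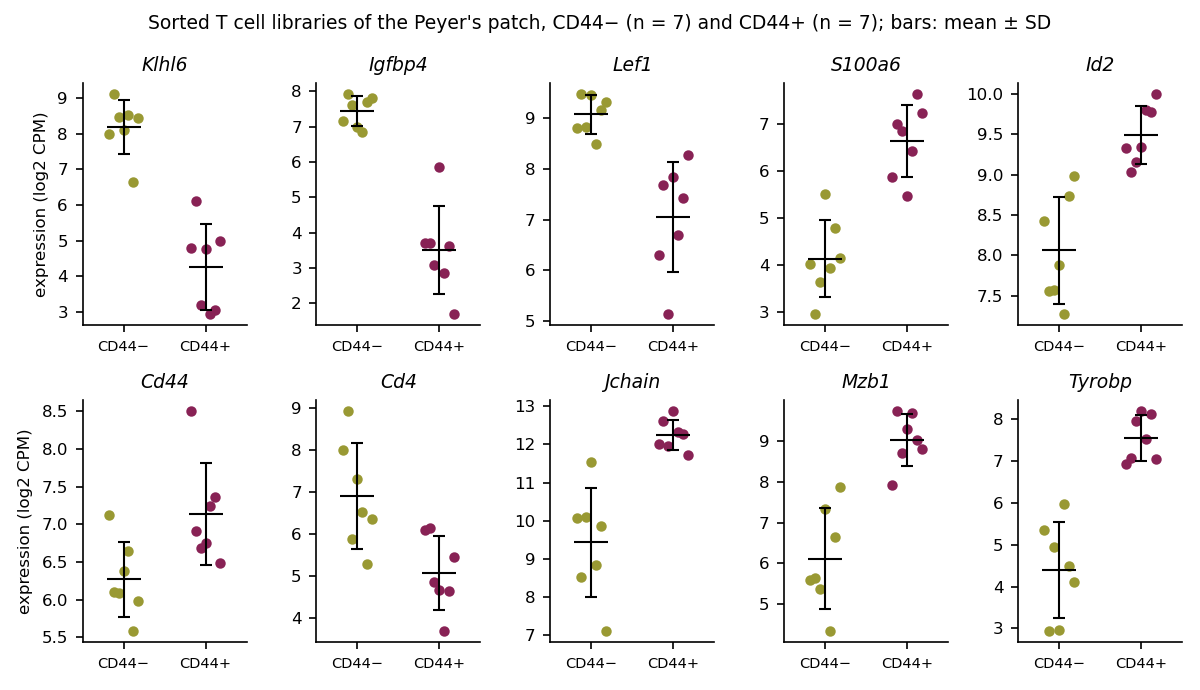
Expression (log2 CPM) of 10 genes in CD44- and CD44+ T cell libraries, with 1 point per library and the mean ± SD as bars (n = 7 per group). Klhl6, Igfbp4 and Lef1 lay lower, and Id2, Jchain, Mzb1 and Tyrobp higher, in every CD44+ library than in any CD44- library, while S100a6, Cd44 and Cd4 overlapped.

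Plasma cell markers rose in 2 of 4 members and 3 adjusted over the list alone. The median was 2.72 (camera adjusted p = 6.04e-06), and the call held with an estimated correlation (0.00616). Mzb1 rose from 93.5 ± 78.0 to 560 ± 221 CPM (2.58 ± 0.48, adjusted p = 0.0122) and Jchain changed by 2.32 ± 0.46 (adjusted p = 0.0193). Both gene calls were lost without CD44- replicate 2 and CD44+ replicate 8 together (0.0516 and 0.0568). Igha, a listed member without exon reads, was not called in total gene reads (0.59 ± 0.65, edgeR adjusted p = 0.788). The rise of Mzb1 and Jchain is therefore not assigned to plasma cells. Gamma-delta T, NK and innate lymphoid markers rose in 1 of 3 members and 3 adjusted over the list alone, with a median of 2.10 (camera adjusted p = 4.69e-05), a call that held with an estimated correlation (0.0106). The member was Tyrobp, which myeloid cells also express and which rose from 26.8 ± 19.6 to 197 ± 72.8 CPM (2.88 ± 0.51). Fcer1g (2.10 ± 0.54) and Klrb1c (1.45 ± 0.63) were not called (adjusted p = 0.0744 and 0.324). In total gene reads the gamma-delta receptor constant genes Trdc (-2.58 ± 1.54, adjusted p = 0.526) and Tcrg-C1 (1.37 ± 0.87, adjusted p = 0.555) were not called. Th17 genes had 0 of 8 members called by edgeR and 3 higher adjusted over the list alone, 3 at an unadjusted p under 0.05, 3 with DESeq2 and 1 with limma-voom. Their median was 1.46 (camera adjusted p = 9.95e-06), and the list's call held with an estimated correlation (0.00616). The smallest p belonged to Tmem176a (2.33 ± 0.60, adjusted p = 0.0781).

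For follicular helper genes, edgeR called 0 of 18 members, with 2 higher adjusted over the list alone, 6 higher at an unadjusted p under 0.05, 4 higher and 1 lower with DESeq2, and 0 with limma-voom. The median was 0.71 (camera adjusted p = 0.00131), with adjusted p = 0.139 with an estimated correlation. Maf was at 172 ± 68.8 and 381 ± 125 CPM (1.14 ± 0.33, adjusted p = 0.114) and Sh2d1a at 808 ± 287 and 1388 ± 292 CPM. For cell cycle genes it called 0 of 29, with 1 higher adjusted over the list alone, 11 higher and 1 lower at an unadjusted p under 0.05, 6 higher with DESeq2 and 0 with limma-voom. The median was 0.79 (camera adjusted p = 0.00465), with adjusted p = 0.139 with an estimated correlation, and Ccnb2 had the smallest p (3.08 ± 0.81, adjusted p = 0.0840). B cell markers had 0 of 12 called, 3 higher adjusted over the list alone, 4 higher at an unadjusted p under 0.05, 2 with DESeq2 and 1 with limma-voom. Their median was 1.17 (camera adjusted p = 0.00731), with adjusted p = 0.285 with an estimated correlation, and the call was lost without CD44- replicate 8 (0.0844). Vpreb3 (2.17 ± 0.52) and Cd79a (1.55 ± 0.44) led that list. Germinal centre B cell markers had 0 of 4 called by each of edgeR, DESeq2 and limma-voom, and 0 with edgeR adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 0, DESeq2 1 higher and limma-voom 1 higher. The median was 1.20 (camera adjusted p = 0.0415), with adjusted p = 0.139 with an estimated correlation, and the call was lost without CD44+ replicate 1, 2, 4 or 6 or CD44- replicate 1, 7 or 8 (0.0550 to 0.105). Myeloid and dendritic markers had 0 of 10 called, 1 higher adjusted over the list alone, 2 higher at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom. The median was 0.25 (camera adjusted p = 0.00651), with adjusted p = 0.364 with an estimated correlation, and the call was lost without CD44- replicate 2 (0.139). Siglech (4.76 ± 1.48, adjusted p = 0.138) and Cst3 (1.66 ± 0.62, adjusted p = 0.237) had the smallest p.

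Mitochondrially encoded genes fell in 3 of 13 members and 10 adjusted over the list alone. The median was -1.11 (camera adjusted p = 1.36e-05), with adjusted p = 0.364 with an estimated correlation. They made up 9.84% ± 4.07 of exon reads in CD44- and 5.62% ± 1.90 in CD44+ libraries. mt-Cytb fell from 16510 ± 14006 to 3005 ± 1100 CPM, and the overlapping genes mt-Atp8 and mt-Atp6, which can share reads, changed by -3.07 ± 0.47 and -2.20 ± 0.39. Outside these lists, among well expressed called genes without overlap between the groups, the largest decreases included Kdelc1, which changed by -4.94 ± 0.90 (chromosome 1 from 44106546 to 44118808, ENSMUSG00000026047), Parn, a poly(A) ribonuclease, by -4.82 ± 0.74 (-1.93 and not called with total gene reads, adjusted p = 0.255), Klhl6 by -3.65 ± 0.54 and Ripor2 by -3.49 ± 0.64. Bcl2a1a, a survival gene that shares reads with near-identical copies, had the largest increase among such genes, 4.58 ± 0.87 (chromosome 9 from 88956900 to 88962419, ENSMUSG00000102037). Ly6d changed by 2.501 ± 0.489. Napsa changed by 2.66 ± 0.60 (adjusted p = 0.0399), a call kept only without CD44+ replicate 1 or CD44- replicate 6, 7 or 8 and otherwise lost (0.0520 to 0.0866).

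The other lists were not called by camera. Survival genes had 1 of 12 higher (3 adjusted over the list alone; camera adjusted p = 0.156), the member being Bcl2a1a. This list was called upward by fry (adjusted p = 0.0322). Co-inhibitory and anergy genes had 1 of 16 lower, Dgka, and amino acid response genes 1 of 15 lower, Nars, both named after their values were seen (2 higher and 1 lower, and 1 lower, adjusted over the list alone; 0.643 and 0.352). Ribosomal protein genes had 2 of 77 lower, Rpl4 and Rpl5, also named after their values were seen (7 lower adjusted over the list alone; 0.321). Counts of called members were 0 by edgeR in all other lists. Adjusted over the list alone, 1 member of the alpha-beta T cell core genes, 1 of the circadian clock genes and 2 of the glucocorticoid response genes were lower, and 0 members of the others passed. The camera adjusted p was 0.648 for alpha-beta T cell core, 0.829 for circadian clock and 0.829 for glucocorticoid response genes, 0.0811 for handling stress, 0.352 for interferon-stimulated and 0.930 for T cell receptor signal genes. It was 0.745 for regulatory T cell, 0.648 for Th1 and cytotoxic, 0.321 for Th2, 0.823 for pro-apoptotic and 0.745 for p53 target genes. It was 0.829 for mucosal homing, 0.829 for aryl hydrocarbon and retinoic acid response, 0.930 for glycolysis and 0.377 for cholesterol synthesis genes. Epithelial, stromal and erythroid markers had 0.533, 0.648 and 0.352. In the lists with 0 called by edgeR, an unadjusted p under 0.05 was found for at most 2 members, except for 1 higher and 5 lower interferon-stimulated genes and 1 higher and 3 lower alpha-beta T cell core genes. DESeq2 called at most 1 member of each of these lists and limma-voom 0. Median or mean and camera's direction differed in sign for T cell receptor signal, Th1, pro-apoptotic, survival, glycolysis, mucosal homing, aryl hydrocarbon, glucocorticoid response and ribosomal protein genes. Of the 2 CD8 markers, Cd8b1 had a log2 fold change of 1.16 ± 0.96 (adjusted p = 0.671) and Cd8a of -0.23 ± 1.51 (0.966). Of 33 lists 11 were called, 9 up and 2 down, and fry called 8. Of the 11, fry did not call mitochondrially encoded genes (adjusted p = 0.190) or B cell (0.0868), germinal centre B cell (0.0730) and myeloid markers (0.141). With an estimated correlation 4 were called, the naive, Th17, plasma cell and gamma-delta T lists.

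The CD44 comparison was then read in the diet libraries, which differ from the CD44 libraries in kit, RNA input and, by Y-linked reads, sex. The CD44 score was built from 25 genes higher and 39 genes lower in CD44+ libraries. It asks whether the diet moved the CD4+ libraries along the difference between CD44- and CD44+ libraries. It averaged -1.10 ± 0.35 (SD) on the conventional diet and -1.05 ± 0.32 on the elemental diet (n = 6 each). The difference of 0.04 was smaller than the spread between libraries (exact two-sided permutation p = 0.812 over 924 assignments). Without cell cycle and B lineage genes in the score the difference was 0.300 (exact permutation p = 0.126). With the genes chosen without CD44- replicate 2 and CD44+ replicate 8 the difference was 0.54 (exact permutation p = 0.0281). Leaving out single libraries moved it between -0.06 and 0.39, below 0 without conventional replicate 1 (-0.06) or 5 (-0.0021), CD44+ replicate 1 (-0.02) or CD44- replicate 5 (-0.02).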

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

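In this part the depth test of the CD44 comparison was set before its result was seen, and the other tests of explanations were chosen after the results they bear on had been seen. Within groups of 6 or 7 libraries, 302 sets of values were searched for a library lying far from the rest of its group, and 16 were found, of which 15 are given here. Chance alone gives about 1 in 20 groups. Of the 16, 4 lay in conventional replicate 6 of the CD4+ libraries.

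In that library mitochondrially encoded genes took 8.56% of exon reads, against 7.08% in the nearest library of its group. Its log2 CPM was 3.92 for Foxp3 (nearest 4.55), 8.59 for Tcf7 (nearest 9.13) and 1.59 for Ifi44 (nearest 0.82). Conventional replicate 3 had a log2 CPM of 2.59 for Tbx21 (nearest 3.17). Elemental replicate 2 had a CD44 score of -1.69 (nearest -0.99). CD44+ replicate 8 had 11053 genes detected (nearest 11861) and a log2 CPM of 8.87 for Cst3 (nearest 6.07). Other CD44+ libraries stood apart in log2 CPM of Pdcd1 (replicate 2, 4.87, nearest 6.55), Fas (replicate 5, -0.29, nearest 4.17) and Cdk1 (replicate 4, 0.83, nearest 3.73). CD44- libraries stood apart in Napsa (replicate 6, -0.032, nearest 3.62), Tnfrsf4 (replicate 6, 4.62, nearest 7.89), Sh2d1a (replicate 2, 7.79, nearest 9.47) and Siglech (replicate 1, 3.56, nearest -1.52). In total gene reads, which the main tests did not use, the immunoglobulin light chain gene Iglc1 was higher in CD44+ cells by a log2 fold change of 2.52 (edgeR adjusted p = 0.0111). Its lowest CD44+ library, at 239 CPM, lay above the highest CD44- library, at 212 CPM. Iglc1 belongs to a family of lambda constant genes, and reads shared with other members were not excluded, so its own level is uncertain.

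Follicular helper genes were lower on the elemental diet together with germinal centre B cell markers, so B cell RNA carried in the sort is a candidate explanation. The 13 members left after setting aside 6 listed as also expressed by B cells fell by 0.73 on the log2 scale relative to the T cell core genes. The exact two-sided permutation p was 0.00216, the smallest that 924 assignments give, for lists whose directions had already been seen. This argues against fewer B cells as the cause only for members that B cells lack. No B cell library was measured to show which of the 13 these are. For the 6 members that B cells also express the difference was -0.68, and there fewer B cells and a change in T cells cannot be told apart, because either would lower these genes. Dilution of T cells by other cells would lower the whole list as much as the T cell core, yet it fell by 0.72 relative to it (exact permutation p = 0.00216). Open are a smaller share of follicular helper cells among the sorted cells and lower expression per cell, either of which the diet could bring about, and bulk libraries do not test them.

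Enterocyte and macrophage genes were higher on the elemental diet although the sort was for CD4. A lower share of T cells alone would raise the markers of every other cell type alike. Yet mean log2 CPM changed by -0.63 for the B cell markers (exact permutation p = 0.0346) and by 2.21 for abundant enterocyte transcripts. B cell markers thus moved by -2.85 relative to enterocyte transcripts (exact permutation p = 0.00216). Both directions had been seen before, so this last p-value adds no support of its own. On lists of abundant transcripts written after the epithelial and myeloid markers had been seen, 25 of 26 enterocyte transcripts had log2 fold changes above 0 and 16 rose (median 1.83), as did 21 of 22 and 18 of the macrophage transcripts (median 1.16). Of these, 7 and 9 stand in the fixed lists, and 15 and 16 already had a geometric mean of 10 CPM or more on the conventional diet. Apoa1 went from 114 ± 88.4 to 499 ± 128 CPM, Fabp1 from 42.6 ± 39.0 to 191 ± 48.8 CPM and C1qa from 46.9 ± 12.5 to 211 ± 102 CPM (n = 6 each), so RNA of enterocytes and macrophages in the sorts may account for the rise, and whether the diet or the tissue preparation brought it was not tested.

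Few genes were called between CD44+ and CD44- cells although naive genes separated the groups. Depth alone is argued against, because the diet libraries thinned to the exon read totals of the CD44 libraries still gave 1904 called genes. An exchange of labels between the groups is argued against by a gap of 0.54 in mean log2 CPM of naive genes between the lowest CD44- and the highest CD44+ library. That this list separates the groups had been seen before. On the first principal component of the most variable genes the groups overlapped. Counting each gene once per group, 11599 cases had a group mean of at least 10 CPM, and 12.6% of them had a library of that group under 0.5 CPM, against 0.0499% in the thinned diet libraries. Transcripts dropping out of single low-input libraries may thus widen the spread, and a mixed make-up of the sorted cells that differs between libraries stays open and was not tested.

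Other assignments of the libraries to groups of the same sizes were fitted in the same way, 100 for each comparison with the real one included. There are 462 possible assignments for the diet and 1716 for CD44. Assignments other than the real one mix the real groups, which can widen their spread and lower their counts. For genes called between diets the real value was 2081 and the highest other 1, which argues against chance among the assignments drawn. For gene lists called between diets chance cannot be excluded, since the real value was 15 and the highest other 18. The median of the other assignments was 7 lists, and 11 of the 100 gave at least as many as the real one. For the CD44 comparison 1 of the 100 assignments, the real one, gave as many genes (64, highest other 2) and as many lists (11, highest other 10). This argues against chance for the genes among the assignments drawn. For the lists the margin was narrow and chance is not excluded.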

How the results depend on the processing

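Total gene reads, the joint omission of 2 libraries per comparison and a score on 100 genes each way by p were chosen after seeing the data. Where no reason is given, the cause was not tested. For the diet, genes called stayed between 1677 and 2862 under RLE or upper-quartile scaling, no filter, a stricter filter, segments left out, unique reads, DESeq2 and total gene reads, against 2081 in the main test. They numbered 347 against a minimum fold of 1.5 (fewer by construction, since small changes are excluded), 4070 with limma-voom, 3379 without conventional replicate 6 and elemental replicate 1, and 1299 to 3865 leaving out single libraries. With all 4 groups in the fit 2 were called, as the spread is then shared with the CD44 libraries, whose coefficient of variation is 0.987 against 0.285. For CD44, 50 to 96 genes were called under the scalings, filters, segments left out, unique reads and limma-voom, against 64. They numbered 30 against a minimum fold of 1.5, 1748 with all 4 groups (sharing the smaller spread of the CD4+ libraries), 815 with DESeq2, 101 with total gene reads, 41 without CD44- replicate 2 and CD44+ replicate 8, and 36 to 87 leaving out single libraries.

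Diet lists called numbered 13 to 15 under every setting run except an estimated correlation, which gave 0. CD44 lists numbered 8 to 12 except with an estimated correlation, which gave 4. The CD44 score difference of 0.043 was 0.154 with RLE, 0.0155 with a prior count of 0.5, 0.300 without cell cycle and B lineage genes (exact permutation p = 0.126) and 0.192 on 100 genes by p (exact permutation p = 0.290). It was 0.54 without CD44- replicate 2 and CD44+ replicate 8 (exact permutation p = 0.0281), and -0.057 to 0.394 leaving out single libraries. Score alternatives with 100 or 500 called genes each way were not run, as 25 higher and 39 lower genes were available.

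Of the named genes, 74 were called for the diet and 18 for CD44, and none of these reversed under any setting. Calls were lost by 43 and 5 against a minimum fold, by 3 and 3 with no filter, by 3 and 1 with total gene reads, by 2 and 5 in the joint omissions, by 0 and 1 with RLE and by all 74 of the diet in the fit of 4 groups. Reversals were in genes that were not called. Gata3 in the diet comparison was -0.085 without conventional replicate 6 and elemental replicate 1, and -0.040 to 0.21 leaving out single libraries. In the CD44 comparison Cxcr5 was 0.11 with RLE, 0.022 with upper-quartile scaling, 0.014 with the stricter filter, 0.021 with unique reads, 0.17 with 4 groups, 0.10 with DESeq2, 0.13 with limma-voom, 0.65 with total gene reads and -0.31 to 0.65 leaving out single libraries. Bcl2l11 was -0.25 with limma-voom, -0.26 with total gene reads and -0.46 to 1.30 leaving out single libraries, and Nr4a1 was 0.0021 with limma-voom. Gata3 was 0.32 with total gene reads, 0.077 in the joint omission and -0.61 to 0.17 leaving out single libraries, over which Pdcd1 ran from -0.029 to 0.44 and Ikzf2 from -0.043 to 0.49. The median log2 fold change of all genes in the CD44 comparison moved from 0.027 to 0.109 with DESeq2 and 0.120 with 4 groups.

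The labels do not say whether a replicate number marks a shared mouse or day, and the data do not show that it pairs the libraries. Same-numbered libraries correlated across genes, as deviations from their group means, by -0.142 to 0.271 for the diet (2 of 6 over 0.1) and -0.042 to 0.115 for CD44 (1 of 7), and 3 of 12 and 2 of 14 libraries correlated best with their own number. With the replicate block 2033 diet genes and 14 diet lists were called, and 37 CD44 genes and 11 CD44 lists. The block took the diet calls of Fas, Hspa1a and Cd22, those of the T cell receptor signal (adjusted p = 0.0706) and Th1 lists (0.0775), and the CD44 calls of Napsa and S100a6. Cxcr5 was 0.77 and Bcl2l11 -0.31 in the CD44 comparison with the block. The score difference kept its value of 0.043 in the blocked sign-flip test (exact p = 0.812). Exon reads were fewest in the CD44 libraries, down to 7180390, where Foxp3 and Tbx21 were too low to be tested.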

Other observations

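The tests and genes below were chosen after seeing the data. Immunoglobulin constant genes have no exon reads in the main measure and were read from total gene reads. On the elemental diet the class-switched heavy chain genes were lower in the CD4+ libraries. Igha, the heavy chain of the IgA that lines the gut, fell from 467 ± 152 to 113 ± 40.0 CPM (log2 fold change -2.05, edgeR adjusted p = 0.00177, n = 6 each). Among the IgG genes, Ighg2b changed by -3.95 (adjusted p = 3.39e-04), Ighg3 by -3.44, Ighg2c by -3.17 and Ighg1 by -2.95, with levels that are uncertain because these paralogs can share reads. Igkc, the kappa light chain, changed by -1.55 (adjusted p = 0.00108). The genes of unswitched antibody had smaller log2 fold changes, with Ighm at -0.33 (adjusted p = 0.0337) and Ighd at -0.24 (adjusted p = 0.489), and the difference between these and the switched genes was not tested. The T cell receptor constant genes Trac (-0.15, adjusted p = 0.102) and Trbc1 (-0.01, adjusted p = 0.918) were not called. In CD44+ libraries Igkc rose from 1704 ± 1699 to 7631 ± 2273 CPM (log2 fold change 2.16, adjusted p = 0.0253, n = 7 each). Igha (0.59, adjusted p = 0.788) and Ighm (-0.49, adjusted p = 0.629) were not called there. Which cells held the Igkc RNA was not tested.

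Genes without exon reads took 0.979% ± 0.160 of total gene reads on the conventional diet and 0.586% ± 0.0367 on the elemental diet, 1.78% ± 0.409 in CD44- and 2.67% ± 0.382 in CD44+ libraries. The 4 Y-linked genes of the sex-linked check held 0 to 4 reads in each CD4+ library and 1035 to 4853 reads in each CD44+ or CD44- library. These reads mark the CD4+ libraries as female and place RNA of male mice in the CD44 libraries. Sex therefore differs between the 2 pairs of groups as well. Foxp3 held 247 to 786 reads in the CD4+ libraries and 1 to 11 in the CD44 libraries, which also differ in kit and input.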
